A study of Mus musculus with 2 samples.

How the data were processed

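The samples were 2 libraries of polyadenylated RNA from mouse megakaryocytes, the blood cells that release platelets. Per the labels, they were primary cells of embryonic day 14.5 with both sexes pooled, and the libraries were sequenced in paired end mode. The labels give the libraries 1 group and replicate numbers 1 and 2, and cite the same biosample and donor for both, so the spread between them may be partly technical. The labels name no second group, so no condition was compared, and no paired fit was made.

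For each library the authors deposited a table of genes and a table of transcripts. The file lists deposited beside them give the assembly as mm10 and the annotation as GENCODE M4. The aligner, the quantifier and their versions are not given in the sources used here. The expected count, per the file headers, is an estimated number of fragments per gene or transcript that need not be whole, since fragments shared between transcripts are divided. Of the deposited expected counts, 3.53% in replicate 1 and 1.43% in replicate 2 were not whole. TPM and FPKM, per the file headers, are the authors' values divided by effective length and scaled to depth, given as maximum likelihood estimates and as posterior means. The deposited interval bounds around the posterior means are a score of the authors' quantifier and were not used. The percent of a gene's level taken by a transcript, deposited by the authors as isoform percentages, was recomputed from the transcript TPM.

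Rows of 43346 Ensembl genes were used. Rows with numeric identifiers (26248, median length 73 bases) and 97 rows of added control sequences were left out of totals and tests. The numeric rows held 15 counts in replicate 1 and 0 in replicate 2, and the control rows held 0 counts. Symbols, positions and GC content came from GENCODE M21 on GRCm38, the same assembly as mm10, matched by Ensembl identifier without version. A symbol and a GC value were found for 42462 genes, or 98.0%.

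The expected counts summed to 42099216 in replicate 1 and 2275922 in replicate 2, an 18.5-fold difference in depth. A count of 0 allows up to 3 counts, or 0.0713 CPM (counts scaled to a fixed library total) in replicate 1 and 1.32 CPM in replicate 2. Exact 95% intervals (Clopper-Pearson, conditional on the summed count) were given for ratios of single genes. Intervals and floors cover counting error only, since fragments without molecular identifiers are not independent molecules.

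A gene was called detected at a mean TPM of at least 1. Correlations across genes used log2(TPM + 1). Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3, which gave TMM factors (1.16 for replicate 1 and 0.859 for replicate 2) and a common dispersion from genes with a mean count of at least 10. Ratios of replicate 2 to replicate 1 were scaled by these factors. For list medians a prior count of 0.5 was added in replicate 2 and a larger one, in proportion to the scaled totals, in replicate 1. No prior count was used for counts of genes past 2-fold and ratios of single genes, which used genes with a mean count of at least 100. DESeq2 1.42.0 gave the alternative size factors. All other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

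A set of 24 gene lists was fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of 397 list entries, 396 were found by symbol or synonym. Joined receptor and alpha granule lists (43 genes) were set against each of 9 lists of other cell types by a two-sided permutation test across genes (100000 resamples) of the difference in mean log2(TPM + 1), with Benjamini-Hochberg adjustment over the 9 tests. Genes are not independent replicates, so these p-values describe the gene sets in these libraries. Each list's median level was placed among 10000 random lists of the same size drawn from detected genes. Each list's median ratio between the libraries was placed among 10000 random lists matched on mean expression in 20 bins, for lists with at least 5 members at a mean count of at least 10. A further list of 34 myeloid and macrophage genes was written after the first look at the files and before it was tested. Dominant transcripts were compared for genes with at least 2 annotated transcripts and a mean TPM of at least 5. Depth was examined by 100 random thinnings of replicate 1 to the total of replicate 2.

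The text names the 20 genes with the highest mean TPM, the 3 highest members and the lowest member of each list (of the lists of other cell types with several members at 0, some of these), members of the megakaryocyte factor, receptor and alpha granule lists under a mean TPM of 1, all globins, all sex-linked genes, the 10 largest and 10 smallest ratios between the libraries, transcripts of megakaryocyte and cytoskeleton genes whose dominant form differed, and transcripts of genes fixed by name, among them Runx1, Gfi1b, Gata1 and Pkm. Values of some single genes that the rule takes in are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

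The steps were tested on simulated data drawn from the real genes, mean shares and totals. Of 186 tested genes changed 4-fold at a coefficient of variation of 0.2, 99.5% were found past 2-fold in the right direction among 7664 genes, and 4.23% of unchanged genes passed as well. The real libraries had a larger estimated coefficient of variation, 0.719, so these rates do not give the error of the 2-fold calls between them. Simulated coefficients of variation of 0.2 and 0.7 were estimated as 0.199 and 0.678. Among simulated lists of 15 genes, 6.25% of unchanged lists fell outside the central 95% of random lists, and 98.3% of lists shifted 4-fold were found. For the marker comparison, 3.25% of equal gene sets reached p under 0.05.

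The alternatives were other TPM thresholds, pseudocounts of 0.1 and 0.01, FPKM, posterior mean TPM, CPM, other count minimums, other scalings, and each library alone. Alternatives added after the data were seen were thinning of replicate 1, a minimum of 50 CPM, removal of the median ratio of each of 20 GC bins, lists without members at 0 in replicate 2, lists with those members at the floor of 3 counts, and 10000 random gene sets matched on mean expression, length, GC content or the last pair together for the ribosomal protein, mitochondrial and histone families.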

Results

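Megakaryocytes from mouse embryos of day 14.5 were profiled by sequencing of polyadenylated RNA in 2 libraries of 1 group. Replicate 1 held 42099216 expected counts and replicate 2 held 2275922. A mean TPM of at least 1 was reached by 9858 genes, of which 9123 were protein coding. That level was met in both libraries by 7863 genes, in replicate 1 alone by 2190 and in replicate 2 alone by 912. TPM values are means ± SD of TPM over the 2 libraries (n = 2) unless a library is named.

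The most abundant transcript was Ftl1, the ferritin light chain, at 28422 ± 6787 TPM. It was followed by Gm42418 at 17409 ± 7030, Rplp1 at 16281 ± 11788, and Laptm5, a lysosomal membrane protein of blood cells, at 13655 ± 16481. Gapdh reached 12376 ± 8854, Pfn1 12109 ± 4079, Rpl18 11561 ± 3369, Actb 11358 ± 3209, Hist1h2ap 11268 ± 57.2 and Ptma 10494 ± 6165. The next 10 genes were Rps15, Hba-a1, Rpl36, Fth1, Cyba, Rpl28, Rplp2, Gpx4, Rps26 and Nrgn, from 8662 ± 1543 for Rps15 down to 6786 ± 1700 for Nrgn. The 10 genes with the most counts in each library, which differ from the 10 highest by mean TPM, took 12% of counts in replicate 1 and 15.6% in replicate 2. Ribosomal protein, histone and globin genes share fragments with near-identical copies, so their single values are uncertain.

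Genes known for megakaryocyte function stood high. All 18 transcription factors of the megakaryocyte list reached a mean TPM of 1, with list medians of 139 TPM in replicate 1 and 266 TPM in replicate 2. Zfpm1, the cofactor of GATA1, was highest at 2184 ± 1402, followed by Gata1 (chromosome X, 7959260 to 7978071, GRCm38) at 648 ± 607 and Runx1 at 616 ± 432, and Cbfb was lowest at 8.36 ± 8.78. Of 25 receptors and adhesion proteins, 22 reached a mean TPM of 1, led by the von Willebrand factor receptor subunits Gp1bb at 5861 ± 2601 and Gp9 at 4710 ± 2878 and by the integrin Itga2b (chromosome 11, 102453297 to 102470122) at 3909 ± 737. P2ry12 (0.745 ± 1.05) and Itga2 (0.07 ± 0.099) stayed below that level, and Cd36 had no counts in either library. Of 18 alpha granule genes, 16 reached it, led by Tgfb1 at 5765 ± 2279, Pf4, platelet factor 4, at 1783 ± 1625 and Clu at 1335 ± 1045. Angpt1 reached 0.93 ± 1.32, and Serping1 had no counts.

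Platelet cytoskeleton genes had median levels of 362 and 172 TPM in replicates 1 and 2, with Fermt3 at 6111 ± 1796, Zyx at 5859 ± 3003, Bin2 at 2351 ± 490 and the lowest member, Dnm3, at 0.035 ± 0.0495. Tubb1, the platelet beta tubulin, chosen after its value was seen, had only 21.5 ± 14.1. Platelet signalling genes (22 of 22 at a mean TPM of 1) were led by Gnai2 at 1577 ± 341, Lat at 618 ± 210 and Rasgrp2 at 565 ± 145, and Pik3cb was lowest at 1.27 ± 0.594. Granule biogenesis genes were lower, with medians of 12.5 and 9.52 TPM, although Stxbp2 reached 604 ± 71.9, Hps4 527 ± 456 and Unc13d 314 ± 145; Hps3 was lowest at 0.185 ± 0.262. Among 10000 random lists of detected genes, the medians of the factor, receptor and cytoskeleton lists lay at percentile 100, alpha granule cargo at 99.98, signalling at 99.96 and granule biogenesis at 75.5. Against random lists of genes at a mean TPM of at least 0.1, granule biogenesis lay at percentile 97.7.

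**Figure D1:**
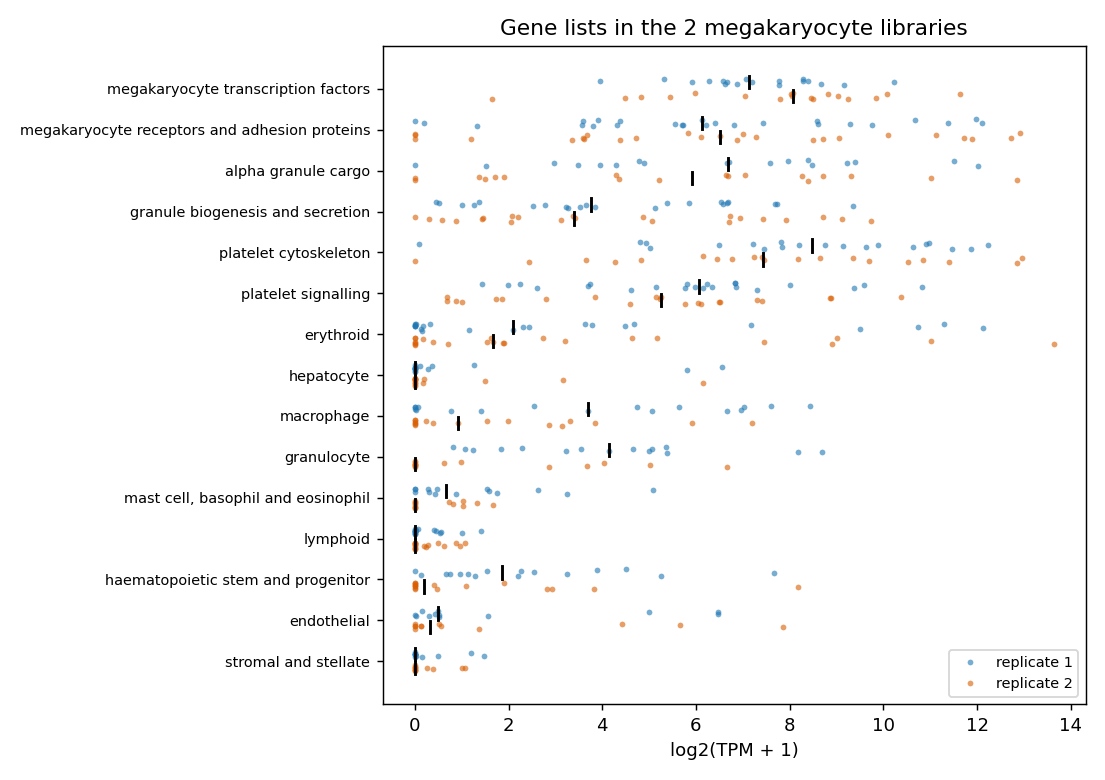
Levels of the genes of 15 lists as log2(TPM + 1) on the horizontal axis, one point per gene and library, with black bars for the median of each list in each library. The factor list has medians of 139 and 266 TPM, and the lymphoid list has medians of 0.

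Markers of other cell types were set against the 43 joined receptor and alpha granule genes, called marker genes here, to compare their levels. These are different genes, and a mixture of cells could still leave the marker genes higher. The differences therefore do not measure how much RNA of other cells the libraries held. In replicate 1 the granulocyte list had a median of 16.74 TPM and the macrophage list 11.98 TPM. In replicate 2 these medians were 0 and 0.88 TPM. The marker genes exceeded every one of the 9 lists in both libraries. The difference in mean log2(TPM + 1) was 5.93 ± 0.15 against stromal genes, 5.92 ± 0.19 against lymphoid genes, 5.38 ± 0.04 against hepatocyte genes, 5.29 ± 0.40 against mast cell, basophil and eosinophil genes and 4.32 ± 0.54 against stem and progenitor genes (each adjusted p = 3.6e-05 by a permutation test across genes, from a raw p of 2e-05, the smallest the resamples can give). It was 4.41 ± 0.11 against endothelial genes (adjusted p = 0.00027, permutation test), 3.48 ± 1.04 against macrophage genes (adjusted p = 0.000874, permutation test), 3.37 ± 1.54 against granulocyte genes (adjusted p = 0.00121, permutation test) and 2.88 ± 0.17 against erythroid genes (adjusted p = 0.00378, permutation test). With lists restricted to members at a mean TPM of at least 1, the comparisons with erythroid (adjusted p = 0.135), hepatocyte (adjusted p = 0.135) and endothelial genes (adjusted p = 0.192) no longer passed the permutation test. Over all alternatives the adjusted p ranged from 0.00114 to 0.135 for erythroid, from 3.6e-05 to 0.135 for hepatocyte and from 0.00012 to 0.192 for endothelial genes. Against granulocyte genes the difference was 2.27 in replicate 1 and 4.46 in replicate 2, and its adjusted p ranged from 0.00015 to 0.0176.

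Among erythroid genes, the adult globins were abundant, with Hba-a1 at 8598 ± 5823, Hba-a2 at 2284 ± 313, Hbb-bt at 1116 ± 853 and Hbb-bs at 604 ± 174, whereas the embryonic globin Hbb-y stood at 2.70 ± 0.849 and Hbb-bh1 and Hba-x had no counts. Summed globins made 9436 TPM in replicate 1 and 15775 TPM in replicate 2. In the macrophage list the complement genes C1qc (245 ± 141), C1qb (125 ± 94.1) and C1qa (71.1 ± 81.8) were highest, and Lyz1, Timd4 and Cd163 had no counts. The granulocyte list was led by Prtn3 (256 ± 221), Mpo (160 ± 181) and Csf3r (26.3 ± 20.7), and Retnlg was lowest at 0.375 ± 0.53. Mecom of the stem and progenitor list, Robo4 of the endothelial list and Mcpt4 and Fcer1a of the mast cell list had no counts. The stem and progenitor list was led by Myc at 247 ± 61.8, Slamf1 at 21.8 ± 21.5 and Cd34 at 13.9 ± 11.02, the endothelial list by Eng at 158 ± 101, Egfl7 at 53.7 ± 47.2 and Tie1 at 40.2 ± 13.3, and the hepatocyte list by Dlk1 at 81.1 ± 16.1, Trf at 31.3 ± 33.1 and Apoa1 at 1.61 ± 0.304. Alb, albumin, and 8 other hepatocyte genes had no counts in either library. Prss34 (17.2 ± 22.3), Hdc (5.34 ± 4.50) and Cpa3 (2.61 ± 3.69) led the mast cell, basophil and eosinophil list. Pdgfrb (1.41 ± 0.544), Reln (1.20 ± 0.156) and Col1a2 (0.36 ± 0.0707) led the stromal list, and no lymphoid gene reached a mean TPM of 1, the highest being Cd79b at 0.925 ± 0.120, Lck at 0.825 ± 1.17 and Pax5 at 0.555 ± 0.785.

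DNA replication genes had medians of 11.8 and 7.75 TPM (percentile 49.3), with Cdt1 at 73.0 ± 15.7, Rrm2 at 43.9 ± 7.45 and Mcm2 at 41.3 ± 2.45, and Cdc6 was lowest at 0.21 ± 0.297. Mitosis and cytokinesis genes had medians of 10.4 and 6.20 TPM (percentile 35.0), led by Arhgef2 at 383 ± 126, Cdc20 at 96.1 ± 6.32 and Plk1 at 88.6 ± 6.20, and Bub1 was lowest at 0.37 ± 0.297. Among G1 regulators (medians of 12.4 and 25.7 TPM, percentile 85.8), Ccnd3, cyclin D3, reached 1190 ± 413, Cdk4 551 ± 359 and Cdkn1a 342 ± 50.8, and Cdkn1c was lowest at 0.285 ± 0.0354. The joint list of hypoxia and glycolysis genes had medians of 115 and 83.4 TPM (percentile 100) and was led by the glycolytic enzymes Gapdh, Aldoa at 4502 ± 837 and Pkm at 2480 ± 57.1, and Adm, a peptide induced by hypoxia, had no counts. Immediate early genes (94.4 and 61.8 TPM, percentile 99.95) were led by Junb at 755 ± 72.2, Zfp36 at 281 ± 33.7 and Jun at 278 ± 179, and Egr2 was lowest at 2.15 ± 2.14. Heat shock genes (39.4 and 14.5 TPM, percentile 96.0) were led by Hspa8 at 901 ± 172, Hsp90ab1 at 356 ± 99.1 and Bag3 at 63.2 ± 32.2, and Hspb1 was lowest at 0.385 ± 0.544. Interferon response genes (7.21 and 0.88 TPM, percentile 4.43) were led by Irf7 at 173 ± 11.9, Bst2 at 148 ± 129 and Ifitm3 at 87.6 ± 82.3, and Ifi44 had no counts. Against random lists of genes at a mean TPM of at least 0.1, DNA replication lay at percentile 90.8, mitosis at 86.9, G1 regulators at 98.7 and interferon response at 49.6. Housekeeping genes had medians of 145 and 49.6 TPM (percentile 99.95), with Rplp0 at 1736 ± 1004 after Gapdh and Actb, and Tbp lowest at 1.15 ± 0.290. The X-inactivation transcript Xist had 821 counts in replicate 1 and 4 in replicate 2. The Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d had 74, 40, 12 and 11 counts in replicate 1 and 0 in replicate 2. By counting error alone, a count of 0 in replicate 2 allows 1.32 CPM.

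The libraries differed widely from each other. Across the 9858 detected genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.816 and Spearman's rho was 0.764. The biological coefficient of variation from edgeR was 0.719 over 12132 genes. Of 8194 genes with a mean count of at least 100, 1288 were at least 2-fold higher and 2767 at least 2-fold lower in replicate 2, including 372 with 0 counts there. In 100 thinnings of replicate 1 to the total of replicate 2, 0 genes at this count minimum fell to 0 counts. Genes pass this count minimum mainly through the deeper replicate 1, which favours lower calls, and with a minimum that gives both libraries equal weight, a mean of at least 50 CPM, the split turned to 680 higher and 407 lower. It also depended on the scaling, with 598 higher and 3567 lower under total counts and 1751 higher and 2178 lower after removal of the GC trend. With 1 library on each side, these ratios compare the libraries and have no replicate check.

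For the ranking of ratios, genes at 0 in replicate 2 were set to the floor of 3 counts, while other genes kept their counts. Ranked so, the 10 smallest ratios included that of Marco, a macrophage scavenger receptor, with 2282 counts in replicate 1 and 1 in replicate 2 (ratio 0.0110, exact 95% interval 0.000278 to 0.0613). They also included those of Snw1, Hsd17b10, Speg, Pirb and Isg15, each with 1 count in replicate 2. Their ratios ran from 0.0154 for Snw1 (interval 0.000391 to 0.0862) to 0.0219 for Isg15 (interval 0.000555 to 0.122). Rpl3-ps1 with 3 counts had a ratio of 0.0164 (interval 0.00337 to 0.0478) and Sem1 with 5 counts one of 0.0221. Gm10163 and mt-Nd4l had 0 counts in replicate 2 and were at least 79.1-fold and at least 76.8-fold lower, against a floor of 3 counts, and the value of mt-Nd4l is uncertain, since other mitochondrially encoded genes were listed at 0 as well. Laptm5 (chromosome 4, 130913125 to 130936141) had 2001 TPM in replicate 1 and 25309 TPM in replicate 2, a ratio of 14.96 (interval 14.8 to 15.1). The other 9 largest ratios were those of Gm7935 (36.4, interval 31.2 to 42.6), Gm4735 (19.7), Gm21738 (17.3), Gm5812 (16.6), Gm10800 (16.2), mt-Nd6 (16.2), Gm10719 (14.3), Gm26870 (13.6) and Gm10801 (13.3). Most of these are pseudogenes or predicted genes that share sequence with other copies, so their values are uncertain.

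**Figure D2:**
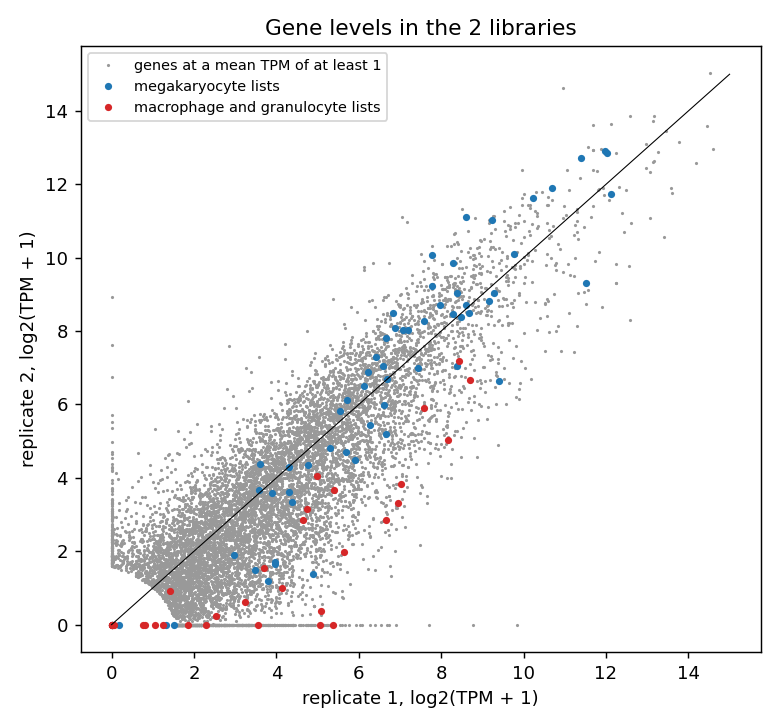
Gene levels in replicate 1 (horizontal) and replicate 2 (vertical) as log2(TPM + 1), with genes of the megakaryocyte factor, receptor and alpha granule lists in blue, macrophage and granulocyte lists in red, and the line of equal levels. Macrophage and granulocyte genes lie mostly below the line, and Pearson's r over all detected genes is 0.816.

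Myeloid genes stood apart between the libraries. Relative to a median log2 ratio of -0.52 over 12131 genes, the macrophage list had a median of -3.02 and the granulocyte list -2.99, both at percentile 0 of random lists, and all 12 and all 14 measured members lay under the all-gene median. Csf1r, chosen after its value was seen, had 48.5 TPM in replicate 1 and 2.96 TPM in replicate 2, and Mpo had 288 and 31.7 TPM. These medians use a prior count for members at 0 in replicate 2 (1 macrophage and 7 granulocyte genes), and with members at 0 set to the floor of 3 counts, in these and in the random lists, they were -2.74 (percentile 0) and -1.63 (percentile 0.07). Interferon response genes had a median of -2.73 (percentile 0.02, 10 of 12 members under the all-gene median), or -1.34 (percentile 0.89) with its 4 members at 0, and those of the random lists, set to the floor. The summed counts of the macrophage, granulocyte and interferon lists had ratios of 0.264, 0.167 and 0.460. These are smaller falls than the list medians with the prior count. Housekeeping genes (-1.53, percentile 0.21) and alpha granule cargo (-1.06, percentile 0.76) also lay below the central 95%, and after removal of the GC trend their medians were -0.61 and -0.18, inside the range of random lists (percentiles 13.3 and 36.8). Without its member at 0 in replicate 2, alpha granule cargo had a median of -0.63 (percentile 3.96), also inside that range. With that member, and those of the random lists, set to the floor, its median was -1.07 (percentile 0.74), below the central 95%. The summed counts of alpha granule cargo were 1.78-fold higher in replicate 2, opposite in sign to the median. Within alpha granule cargo, Pf4 had a ratio of 0.249, while Clu had 4.11 and Tgfb1 2.10. No list of the 21 tested lay above the central 95%; the highest medians were those of the factor list (0.56, percentile 83.4) and the receptor list (0.36, percentile 86.8). Gata1 of the factor list had a ratio of 5.80.

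**Figure D3:**
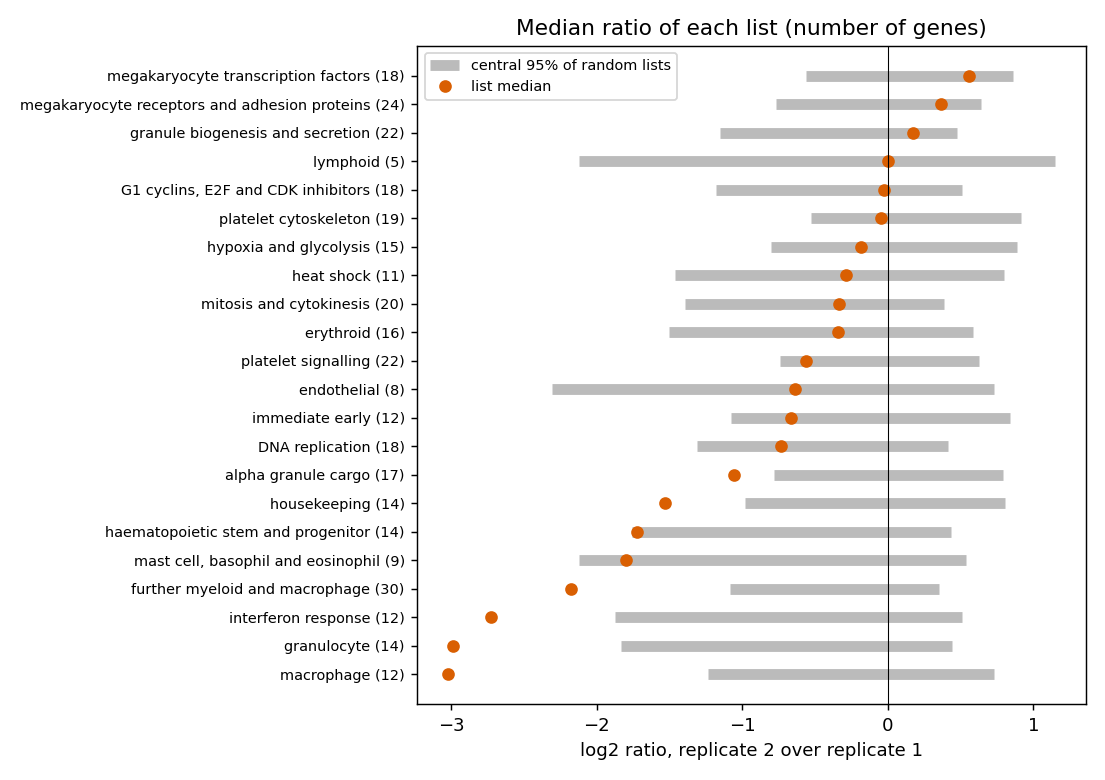
Median log2 ratio of replicate 2 over replicate 1 for each list (points) and the central 95% of 10000 random lists matched on mean expression (grey bars), with the number of genes in parentheses. The macrophage list at -3.02 and the granulocyte list at -2.99 lie left of their bars.

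Cytosolic ribosomal protein genes summed to 189895 TPM in replicate 1 and 84004 TPM in replicate 2. Of 80 measured members, 74 were lower in replicate 2, with a median log2 ratio of -1.91. Total counts in place of TMM moved the median of all genes from -0.52 to -0.94, and 65 of the 80 lay under the all-gene median. Short genes and genes of low GC content had lower ratios in general, and random gene sets matched on length and GC content, a comparison chosen after the data were seen, had a typical median of -1.16 (central 95% from -1.62 to -0.56), above that of the ribosomal protein genes (percentile 0.04, and percentile 0 with sets matched on length, GC content or mean expression alone). Of the mitochondrially encoded genes, 7 of 10 measured members lay under the all-gene median, and their median of -1.60 lay at percentile 0.29 of sets matched on mean expression but at percentile 47.3 with GC content, 15.8 with length and 51.6 with both. Among these genes, which every cell uses, mt-Co2 was listed at 0 counts in both libraries, mt-Co3 at 0 and 1 and mt-Atp6 at 2539 and 0, so their values are uncertain and their sum was not taken as a level. Histone cluster genes summed to 15236 and 16765 TPM, with a median log2 ratio of 0.14 that turned to -0.29 under total counts. It lay at percentile 99.7 of sets matched on mean expression, 100 with length and 99.8 with length and GC content, but at 63.5 with GC content alone.

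Transcript tables showed the same dominant transcript in both libraries for 3108 of 4695 genes (66.2%, exact 95% interval 64.8 to 67.6). The share was 62.3% for genes under 100 counts in replicate 2 and 76.5% for those with at least 1000. Runx1-203 took 94.0% and 98.6% of Runx1 TPM, Gfi1b-204 94.6% and 90.2% and Pkm-201 98.9% and 99.2%, and Gata1-201 took 100% in both. Of 57 megakaryocyte and cytoskeleton list genes compared, 12 differed, namely Tpm1, Tpm4, Lmo2, Itga2b, Itgb3, Cd9, Clec1b, Itga6, Itgb1, Pecam1, Sparc and Flna. Itgb3-201 took 100% of Itgb3 TPM in replicate 1 and 27.4% in replicate 2, from 365 of 1091 counts. For Itga2b, the 623-base Itga2b-207 led in replicate 1 by TPM (54.6%) with 46272 of 198388 counts, since TPM divides by length. The coding Itga2b-201 led in replicate 2 by a narrow margin, with 37.7% against 36.9% for Itga2b-207. By counts Itga2b-201 exceeded Itga2b-207 in both libraries, with 115826 against 46272 in replicate 1 and 7815 against 1105 in replicate 2. The dominant forms of Clec1b, Pecam1 and Sparc in replicate 2 rest on 13, 6 and 2 counts of the gene.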

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

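The tests of erythroid cells and of carried-over globin RNA were chosen only after the values were seen. Rows with numeric identifiers, which no comparison of the report uses, held 15 counts in replicate 1 and 0 in replicate 2. Their median length is 73 bases. The 15 counts are a sum over 26248 rows, so the floor of 3 counts for a single gene is no measure for them. At the lower depth of replicate 2, its 0 counts do not set the libraries apart.

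Macrophage and granulocyte genes were lower in replicate 2, and removal of the GC trend left the median log2 ratio of the joined lists at -2.64, below the range of random lists matched on GC (-0.79 to 0.66), which argues against GC content as the whole cause. Random loss of counts at the lower depth, taken alone, is argued against as well, since 0 of 100 thinnings of replicate 1 to the total of replicate 2 came as low. Thinning keeps the shares of replicate 1 and adds no variation between libraries. It therefore cannot decide on other losses in replicate 2. A candidate explanation is a smaller share of myeloid cells in replicate 2, since a further list of 30 measured myeloid and macrophage genes had a median of -1.80 after removal of the GC trend (percentile 0), with Gpnmb at a ratio of 0.117 and Tyrobp at 0.108 (the genes of this list named here were chosen after their values were seen). With its 10 members at 0 set to the floor of 3 counts the median before that removal was -1.66 in place of -2.17. Its most abundant member, Lgals3, had a ratio of only 0.814, and Cebpb (2.06) and Cebpa (1.59) were higher in replicate 2, so the list did not move as a whole, and 0 of its genes stand in another list. The summed counts of this further list had a ratio of 0.652, a smaller fall than its median. The labels cite the same biosample and donor for both libraries, and whether their cells differed was not tested.

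More genes were missing from replicate 2 than its depth predicts. It held 11658 genes with a rounded count, under the 12554 to 12745 genes of 100 thinnings of replicate 1. GC content was related to the ratio across genes (rho = 0.294), but removing its trend lowered the SD of log2 ratios by only 3.97% (95% bootstrap interval 3.46 to 4.50). Gene length had a rho of 0.116, and its removal lowered the SD by 0.459%. Neither trend accounts for the spread of ratios over all genes. That spread does not measure how many genes were lost, so a part of GC content in the loss stays open. Median log2 ratios ran from -1.59 in the bin of lowest GC content to 0.563 in the highest. GC removal lowered the share of lower calls among genes past 2-fold from 68.2% to 55.4%. A low number of RNA molecules entering the library was not tested, and no biological explanation was tested.

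Globins were abundant, while 8 other genes of the erythroid list, picked after they were seen near 0, summed to at most 0.0411% of the summed globin TPM. All 16 non-globin genes of the list summed to 2.37% in replicate 1 and 1.63% in replicate 2, so erythroid cells mixed into the samples are not excluded and stay open. That sum rests mostly on Epor, at 143 TPM in replicate 1 and 174 TPM in replicate 2. The next highest were Fech (21.3 and 35.2 TPM) and Sptb (24.8 and 24.0 TPM), so the sum is weak ground for such cells. Loss of those 8 genes by GC content is argued against by their median GC content, which lay at percentile 33.7 of detected genes. Globin RNA carried over from 1 source would keep 1 ratio of alpha to beta globin, and the ratio was 5.20 times as high in replicate 2, or 3.32 times after removal of the GC trend, but 12.35% of random gene sets matched on expression shifted at least as far (24.9% after that removal), so carry-over stays open. Globin transcription in the megakaryocytes themselves was not tested and stays open, and shared fragments between the globin copies limit these values.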

How the results depend on the processing

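Tests and values under thinning, a minimum of 50 CPM, GC removal, lists without members at 0 and lists with those members at the floor were chosen after the data were seen. Of the values that answer a comparison, 111 stayed on their side of the threshold or within the allowed change, 8 moved and 3 lost significance. The allowed change was 1.5-fold for counts of genes, 1.1-fold for the coefficient of variation, 5 points for percentiles of lists, 1 SD between the libraries for list levels and the 95% interval for correlations. Of other values, 184 stayed, 9 moved, 3 lost and 1 gained a call; 15 list ratios changed sign, 0 of them of lists outside the random range. The cause was not tested except where fewer genes entered by construction. A TPM threshold of 5 left 6437 detected genes. With only members at a mean TPM of at least 1, the marker difference was 1.64 against 14 erythroid genes, 2.89 against 3 hepatocyte genes and 2.11 against 4 endothelial genes, and the lymphoid list had no member left. A pseudocount of 0.1 gave r = 0.712, and no filter gave a coefficient of variation of 0.810. Genes past 2-fold numbered 6993 of 12131 at a mean count of at least 10, 1260 of 2948 at 1000 and 1087 of 2576 at 50 CPM, where higher calls outnumbered lower ones (680 and 407). The share of lower calls was 68.2% with TMM, 85.6% with total counts and 55.4% after GC removal. GC removal left 3 of 5 lists outside the random range. Same dominant transcripts numbered 1885 of 2715 genes at a TPM of 20. For single libraries, detected genes ranged from 8775 to 10053. A list median in 1 library lies within 1 SD of a mean of 2 by construction, which says nothing of stability. Such medians could not move, yet they are counted among the values that stayed. Depth limited replicate 2, where genes under 1.32 CPM could be missed by counting error alone. Losses went beyond that floor, since 372 genes at a mean count of at least 100 had 0 counts there, against 0 in the thinnings. Thinned replicate 1 correlated at 0.991 with its full library, but it is a part of that library, so a high value was given in advance. Against replicate 2, r was 0.810 for thinned replicate 1 and 0.816 for the full library.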

Other observations

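The tests of reads divided among copies were chosen after values were seen. Among the largest ratios were Gm10800, Gm10801, Gm21738, Gm10719 and Gm26870, predicted genes that share 25-base words with one another. A candidate explanation is genomic DNA in replicate 2, on the premise, not tested here, that blood cells use few olfactory receptor genes. Those genes took 20.5 times the share of total counts, without TMM scaling, that they took in replicate 1 (exact 95% interval 15.5 to 27.1), with 112 counts over 1026 genes against 101. Counts cluster on genes, and resampling genes widened this interval to 10.5 to 45.7. Vomeronasal receptor genes, tested as a further family, gave a ratio of shares of 14.1 (interval 9.85 to 20.1; 4.67 to 68.2 by resampled genes). Reads moved to these 5 from the other copies would lower the share of the other 7 gene models that share sequence, but it was 10.4 times as high in replicate 2 (275 against 487 counts, interval 8.98 to 12.1; 8.59 to 19.8 by resampled genes), which argues against a division among these models as the cause. Pooled over all 12 models, most of whose counts lie on the 5, the share was 10.9 times as high.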
